A study of Mus musculus with 12 samples.

How the data were processed

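The series profiles transcription factor binding in bone-marrow-derived macrophages of C57BL/6J mice, which are primary macrophages grown from bone marrow. Cells were stimulated with lipopolysaccharide (LPS), a component of the outer membrane of Gram-negative bacteria, for 0, 3 or 8 h. Chromatin was immunoprecipitated with antibodies against RelA, a DNA-binding subunit of NF-kB, or Ikaros, a zinc finger protein encoded by Ikzf1, and sequenced single-end, per the labels' protocols. The labels list 12 samples in 12 groups, and 10 of them had a file used here. These are RelA at each time in wild-type cells, RelA at each time in cells labelled as littermate controls, Ikaros at each time in wild-type cells, and input DNA of untreated wild-type cells. The input samples of the littermate and the Ikaros-knockout animals were not analysed here. File names held another time than the labels for 6 of the samples, and the labels were used throughout, so every comparison of times rests on them. The file names of the wild-type RelA and Ikaros samples labelled 0 h give only 3 h. Those of the wild-type RelA and Ikaros samples labelled 8 h, and of the littermate RelA samples labelled 3 and 8 h, give the labelled time and another time beside it.

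Each file lists hotspots, which are regions enriched for sequence tags, called in a single library. Coordinates are on mm9, per the submitters' processing notes, which also name CASAVA. The aligner, the hotspot caller, its threshold and any subtraction of input are not given in the sources used here, nor is it stated whether a start coordinate counts from 0 or from 1, so coordinates are printed as deposited. For each hotspot the authors deposited the highest and the mean tag density, a signal whose scale is not stated. They also deposited a z score of the region, per the file headers, and the p-value that goes with it. The lowest z score in any file was 8.64 and every file thus held only regions past a threshold set by the authors. The lowest z score differed between files. At 0, 3 and 8 h it was 9.93, 8.88 and 10.9 for wild-type RelA, and 10.9, 8.64 and 10.5 for littermate RelA. For Ikaros it was 9.90, 9.82 and 9.75. The z score was used to rank and describe hotspots within a list, and z scores printed for a region in several libraries are not a measure of change between them.

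The number of reads per library is unknown. The deposited densities below 20 were examined for the value of a single tag. In input they were all whole multiples of 0.312 to within 0.0006. In 8 of the 9 immunoprecipitated libraries between 98.0% and 99.6% of them lay on a grid of a main step less up to 10 times a smaller step, against 81.1% in the wild-type RelA 0 h library with only 37 such values. With other smaller steps the median share on the grid was between 3.78% and 58.1%. The main step was between 0.815 and 0.979 in the immunoprecipitated wild-type libraries, 1.14 in the littermate libraries at 0 and 8 h, and 0.486 in the littermate library at 3 h. If densities were scaled to a common total, which is not stated, the littermate 3 h library would be 2.34 times as deep as that at 0 h. No count of reads was derived from these steps.

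Hotspots that overlapped a hotspot of the wild-type input by 1 bp or more were removed from every list. Hotspots of different lists were called shared when they overlapped by at least 1 bp, and shares were counted in each direction because a region can meet several others. Each share carries an exact Clopper-Pearson 95% interval, and the difference between kept and not kept RelA hotspots was judged by a normal approximation. For comparison, the list searched was moved 1000 times by a random distance along each chromosome, wrapping at its end, and the share was counted again. The highest end coordinate in any file stood in for the length of each of the 21 chromosomes. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9. On simulated lists of 2000 regions with 600 planted overlaps, all 600 were found, the 612 regions found in all equalled the count from bedtools 2.31.1, and shifting gave a mean share of 0.879% against 0.870% calculated.

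Every group holds 1 library, so there is no spread between replicates, no p-value between conditions is given, and no library could be left out within a group. Intervals cover counting error over hotspots alone, and neighbouring hotspots are not independent. Wild-type and littermate animals carry different genotype labels and were kept as separate series. Genotype label, animals and library preparation are confounded between them.

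Before the data were examined, the comparisons, the main settings and the rule for named regions were fixed. That rule took the nearest gene for each region. The gene table at hand is of the GRCm38.p6 assembly while the files are on mm9, so no gene was assigned, and the planned counts of gene list members and of promoters near hotspots were not run. The fallback in the rule names the first 5 regions of each class by coordinates. It was read as the 5 regions ranked first by z score in the class, given by their coordinates. Alternatives were lists as deposited, a reciprocal overlap of at least 50%, a distance of up to 500 bp, the upper 50% of each list by z score for numbers and for shares over time, and lists of equal length for the other shares. After the data were seen, the upper 50% by z score was also applied to shares between series and with Ikaros. A floor on the highest density of a hotspot at 10 was added then in all libraries, as were equal lists by density, removal of broad hotspots of 2000 bp or more, the use of the wild-type series alone, and Ikaros lists held to the same number of hotspots at all times. The share of 8 h RelA hotspots present at 3 h, shares with Ikaros lists of another time, shares of Ikaros hotspots with RelA, the division into quintiles of z score, the comparison of RelA hotspots kept and not kept at 8 h, and the description of broad hotspots were also chosen after the data were seen.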

Results

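Binding of RelA and Ikaros was mapped in macrophages before LPS and 3 and 8 h after it, to follow where each factor sits on chromatin through the inflammatory response. After removal of input hotspots, RelA lists of wild-type cells held 47 hotspots at 0 h, 4972 at 3 h and 1878 at 8 h. RelA lists of littermate control cells held 5805, 9999 and 5231, and Ikaros lists of wild-type cells held 853, 7109 and 13796. Input DNA of untreated wild-type cells gave 765 hotspots. There were no replicates, and each interval below is a 95% exact Clopper-Pearson interval for counting error. Depth per library is unknown. Libraries differed in how weak a hotspot they listed. In both RelA series the 3 h list reached the lowest z scores, so numbers of hotspots at different times rest on unlike cuts. The median of the highest density was between 18.5 and 25.5 in the wild-type RelA and Ikaros lists and between 4.11 and 4.56 in the littermate lists. That median corresponded to 4.00 density steps in the littermate libraries at 0 and 8 h, 8.45 at 3 h, and 22.7 in the wild-type RelA library at 3 h.

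**Figure D1:**
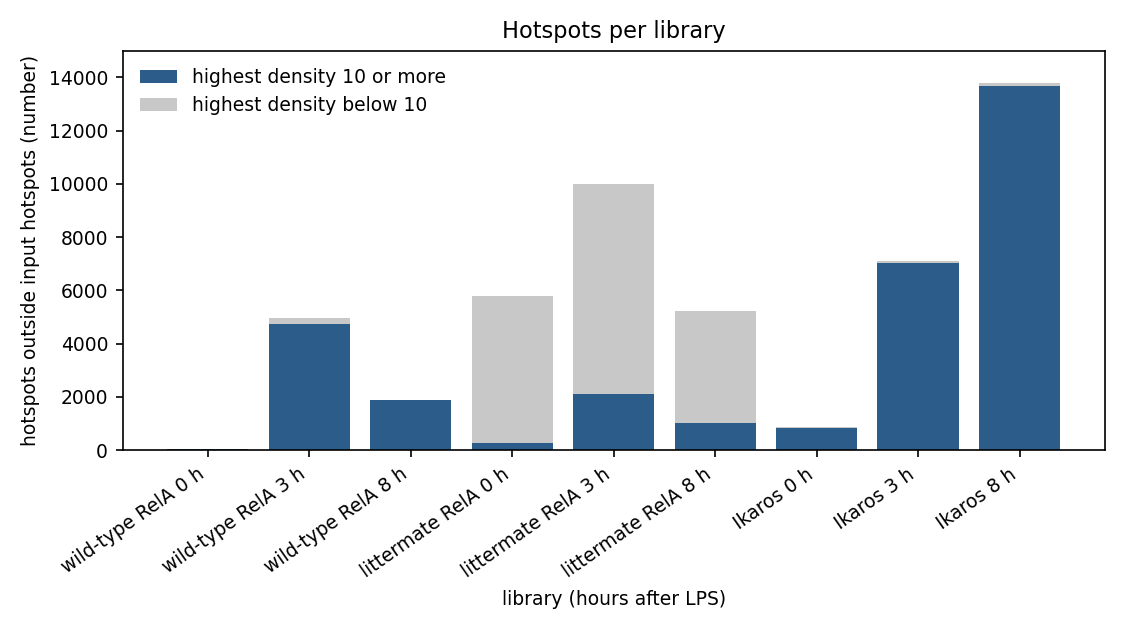
Number of hotspots outside input hotspots in each of the 9 immunoprecipitated libraries, with hotspots of highest density 10 or more in blue and weaker ones in grey. Weaker hotspots made up 95.4% of the littermate list at 0 h, 79.1% at 3 h and 80.4% at 8 h, and at most 4.40% of any wild-type list from 3 h on.

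RelA was listed at very few places in unstimulated wild-type macrophages and at many more after LPS. The wild-type list was 106 times as long at 3 h as at 0 h, and only 37 of its 4972 hotspots, 0.744% (0.525 to 1.02), were already present at 0 h. Of the 47 hotspots at 0 h, 37 were still present at 3 h, 78.7% (64.3 to 89.3). In both series, 1565 regions were listed for RelA at 3 h and not at 0 h. Among them, the strongest by wild-type z score lay on chromosome 19 at 22022084 to 22023086 (z 104), on chromosome 19 at 6945023 to 6946053 (z 98.7), on chromosome 11 at 117807380 to 117808507 (z 93.4), on chromosome 5 at 44272856 to 44274091 (z 80.8) and on chromosome 17 at 26671788 to 26672874 (z 79.5). A further 25 regions carried RelA at all 3 times in both series. These were among the strongest RelA regions at 3 h, with a median z of 59.0 against 12.9 for the whole list. They included chromosome 17 at 13202574 to 13203628 (z 111), chromosome 7 at 25905111 to 25906102 (z 86.0), chromosome 11 at 59354491 to 59356649 (z 85.9), chromosome 10 at 37057707 to 37058936 (z 84.8) and chromosome 3 at 131360829 to 131361842 (z 82.3).

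Random shifts of the 0 h list met at most 0.0201% of the wild-type 3 h hotspots. In the littermate series the 3 h list was 1.72 times as long as that at 0 h, and 7.95% (7.43 to 8.50) of 3 h hotspots were present at 0 h. With hotspots of highest density 10 or more alone, the littermate lists held 265 hotspots at 0 h and 2091 at 3 h, a ratio of 7.89. The littermate density step was 1.14 at 0 h and 0.486 at 3 h, so this floor stood at 8.78 and 20.6 steps. Neither littermate ratio was corrected for these unlike steps. Of those 265, 65.3% (59.2 to 71.0) were in the wild-type 3 h list at this floor and 10.6% (7.14 to 14.9) in the wild-type 0 h list. Absence from the wild-type 0 h list therefore cannot be taken as absence of RelA. Of the wild-type 0 h hotspots as deposited, 36 of 83 overlapped input.

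In wild-type cells RelA was by 8 h no longer listed at most of the places it occupied at 3 h, and few others had appeared. Of the 4972 wild-type 3 h hotspots, 1556 remained at 8 h, 31.3% (30.0 to 32.6). Of the 1878 hotspots at 8 h, 1576 had been present at 3 h, 83.9% (82.2 to 85.6). Retention followed strength, rising from 6.93% (5.44 to 8.69) in the weakest quintile of 3 h hotspots to 77.1% (74.3 to 79.7) in the strongest. Regions bound at 3 h in both series and at 8 h in neither numbered 482. Those ranked first by z score were chromosome 12 at 120345864 to 120346821 (z 53.5), chromosome 3 at 148882750 to 148883835 (z 47.9), chromosome 3 at 107578449 to 107579446 (z 45.9), chromosome 4 at 104941023 to 104941924 (z 44.5) and chromosome 5 at 139307631 to 139308467 (z 42.2). In contrast, 732 regions carried RelA at 3 and 8 h in both series.

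Shifted lists met 0.0880% of 3 h hotspots on average and 1.69% at most. The lists cannot separate a lost site from one that slipped under the threshold. In wild type the lowest z score listed was 8.88 at 3 h and 10.9 at 8 h. The weakest quintile at 3 h ended at 9.97, and the next had a median of 10.7, also below the lowest z score listed at 8 h. Low retention in both may partly follow from these unlike cuts. So may the share retained over all hotspots and its rise with strength. In the littermate series 14.4% (13.7 to 15.1) of 3 h hotspots were present at 8 h and 27.6% (26.4 to 28.8) of 8 h hotspots at 3 h. With hotspots of highest density 10 or more alone, these shares were 40.8% (38.7 to 42.9) and 83.1% (80.7 to 85.4). In the littermate libraries this floor stood at 20.6 density steps at 3 h and 8.77 at 8 h, so it was not the same number of steps.

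Most of the strongest wild-type RelA regions were also in the littermate list. At 3 h, 1712 of the 4972 wild-type hotspots were found in the littermate list, 34.4% (33.1 to 35.8), and the share rose from 8.34% (6.70 to 10.2) in the weakest quintile to 80.4% (77.8 to 82.8) in the strongest. In the other direction 1732 of the 9999 littermate hotspots were in the wild-type list, 17.3% (16.6 to 18.1). That share was 79.9% (78.1 to 81.6) in the densest quintile of littermate hotspots, 6.50% (5.46 to 7.67) in the next, and at most 0.200% in the others. Across quintiles of littermate z score it ran only from 13.3% (11.9 to 14.9) to 21.4% (19.6 to 23.3). At 8 h, 44.0% (41.7 to 46.3) of wild-type hotspots were in the littermate list, and at 0 h 61.7% (46.4 to 75.5) of 47. Of littermate hotspots, 15.8% (14.8 to 16.8) were in the wild-type list at 8 h and 0.500% (0.335 to 0.717) at 0 h.

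With hotspots of highest density 10 or more alone, 10.6% (7.14 to 14.9) of littermate hotspots were in the wild-type list at 0 h, 78.1% (76.3 to 79.9) at 3 h and 80.1% (77.5 to 82.5) at 8 h. The wild-type 0 h list held only 37 hotspots at this floor, which limits the share at 0 h. When both lists were held to equal length, the share of wild-type hotspots in the littermate list was 19.1% at 0 h and 19.2% at 3 h by z score, and 38.3% and 34.4% by highest density.

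Ikaros already occupied 853 regions in resting cells, most of which overlapped an Ikaros hotspot after LPS by 1 bp or more, and its list grew at each time. Of the 853, 757 were present at 3 h, 88.7% (86.4 to 90.8), and 801 at 8 h, 93.9% (92.1 to 95.4), or 68.3% and 62.7% under a reciprocal overlap of at least 50%. Of the 7109 hotspots at 3 h, 82.1% (81.2 to 83.0) were present at 8 h. Of the 13796 hotspots at 8 h, 42.2% (41.4 to 43.1) had been present at 3 h and 7914 were at neither earlier time. Regions with Ikaros at all 3 times numbered 735. The strongest was a broad region on chromosome 17 at 35334713 to 35339904 (z 214 at 3 h), which also carried RelA at 3 and 8 h. The next were narrow regions without RelA in any list, on chromosome 8 at 3754148 to 3754794 (z 176), chromosome 10 at 11211582 to 11212153 (z 175), chromosome 3 at 61962875 to 61963440 (z 172) and chromosome 13 at 113368245 to 113368605 (z 137).

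Hotspots seen only at 8 h were weaker, with a median z of 12.5 against 14.4 for the whole 8 h list. The strongest lay on chromosome 9 at 18272307 to 18273140 (z 43.8), chromosome 2 at 130556279 to 130557043 (z 38.4), chromosome 5 at 147617227 to 147618018 (z 36.4), chromosome 7 at 120181281 to 120181981 (z 35.6) and chromosome 9 at 110759023 to 110759973 (z 35.4). Shifted lists met 0.640% of the 3 h hotspots on average for the 8 h list. The density step was 0.878 at 0 h, 0.958 at 3 h and 0.857 at 8 h.

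**Figure D2:**
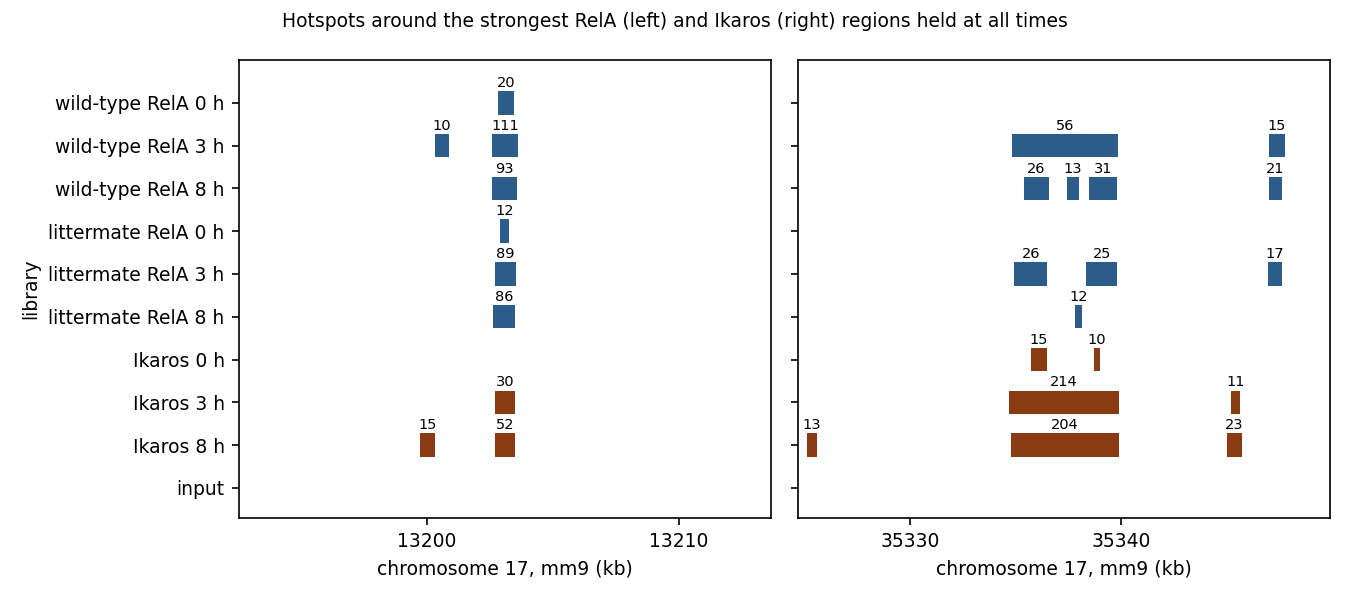
Deposited hotspots in each library (bars, to scale, number above each bar its z score) within 10000 bp of the strongest region with RelA at all 3 times in both series (left) and of the strongest region with Ikaros at all 3 times (right), on mm9 coordinates in kb. The right-hand region holds 2 narrow Ikaros hotspots at 0 h (z 15.3 and 9.98), a hotspot that spans both at 3 h (z 214) and at 8 h (z 204), and no input hotspot.

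After LPS, RelA and Ikaros were listed at many of the same regions in wild-type cells, counting any overlap of 1 bp between the full lists. At 3 h, 2684 of the 4972 wild-type RelA hotspots overlapped an Ikaros hotspot of the same time, 54.0% (52.6 to 55.4), and at 8 h 1511 of 1878 did, 80.5% (78.6 to 82.2). Of RelA 3 h hotspots, 5.51% (4.89 to 6.18) fell on the 853 Ikaros hotspots of resting cells, and 11.4% (10.6 to 12.3) and 10.3% (9.45 to 11.2) on the 853 strongest Ikaros hotspots of 3 and 8 h. Seen from Ikaros, 37.1% (35.9 to 38.2) of 3 h hotspots carried RelA at 3 h and 10.8% (10.3 to 11.4) of 8 h hotspots carried RelA at 8 h. The centres of overlapping hotspots lay a median of 66.5 bp apart at 3 h and 61.0 bp at 8 h. Regions with RelA in both series and Ikaros at 3 h numbered 1140. Ranked first were chromosome 10 at 77597384 to 77599198 (RelA z 122, Ikaros z 49.3), chromosome 17 at 13202574 to 13203628 (111 and 30.2), chromosome 2 at 167602606 to 167603704 (110 and 73.4), chromosome 10 at 18734572 to 18735829 (110 and 28.4) and chromosome 19 at 22022084 to 22023086 (104 and 24.5).

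Overlap with Ikaros rose with RelA strength, from 36.0% (33.0 to 39.1) in the weakest quintile to 77.5% (74.8 to 80.0) in the strongest for Ikaros at 3 h. Shifted Ikaros lists met 0.325% of RelA 3 h hotspots on average and 0.664% at most. When both 8 h lists were held to the 1878 strongest hotspots by z score, 27.8% of RelA hotspots overlapped Ikaros. The full Ikaros list at 8 h held 13796 hotspots, so this setting left out most of it. With the 8 h Ikaros list held to the 7109 strongest, the length of the 3 h list, the share at 8 h was 61.8% (59.6 to 64.0). For littermate RelA against wild-type Ikaros the share at 3 h was 12.6%, and 57.7% (55.5 to 59.8) with hotspots of highest density 10 or more alone.

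**Figure D3:**
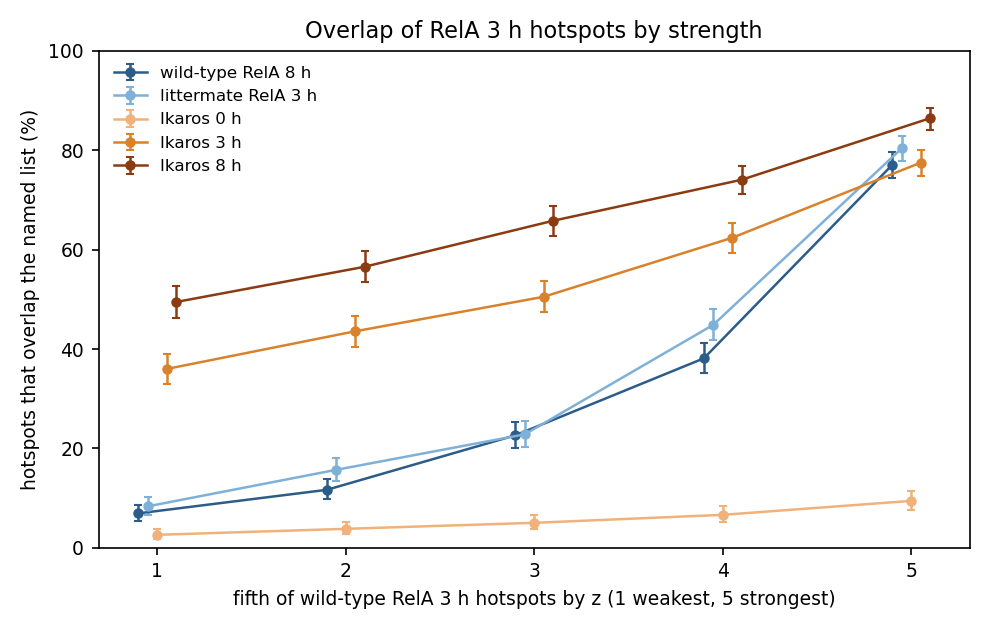
Share of wild-type RelA 3 h hotspots, in %, that overlap each named list, by quintile of z score from 1 (weakest) to 5 (strongest), with 95% exact intervals as bars. The share with Ikaros at 3 h rises from 36.0% to 77.5% and the share present in the RelA 8 h list from 6.93% to 77.1%. The share with Ikaros at 0 h rises from 2.61% to 9.45%, for a list of 853 hotspots against 7109 at 3 h.

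RelA regions that persisted to 8 h carried Ikaros at 8 h more often than those that did not. Of the 1556 wild-type RelA 3 h hotspots kept at 8 h, 84.5% (82.6 to 86.3) overlapped an Ikaros 8 h hotspot, against 58.2% (56.6 to 59.9) of the 3416 not kept. Within each of the 5 quintiles of RelA z score the kept hotspots had the higher share, by between 10.4 and 24.7 percentage points. The 3 h Ikaros list did not part them in this way in wild-type cells. There the shares were 63.5% (61.0 to 65.9) and 49.6% (48.0 to 51.3) over all hotspots, but kept hotspots were higher in 1 of 5 quintiles. Kept minus not kept ran from -9.55 to 3.39 percentage points. The middle quintile had the lowest value, with 43.1% (36.5 to 49.9) of kept and 52.7% (49.1 to 56.2) of other hotspots. In the strongest quintile the shares were 77.4% (74.3 to 80.4) and 77.6% (71.7 to 82.9). Of the 482 regions bound by RelA at 3 h in both series and at 8 h in neither, 72.6% (68.4 to 76.5) carried Ikaros at 8 h. Of the 732 with RelA at 3 and 8 h in both series, 90.6% (88.2 to 92.6) did. The 482 were weaker, with a median RelA z of 14.3 at 3 h against 26.7 for the 732. These shares were not matched for strength, with which overlap with Ikaros rose. Among the 5 named regions of the 482, 4 carried Ikaros at 8 h. The exception was chromosome 12 at 120345864 to 120346821, which had Ikaros at 3 h.

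Among littermate hotspots of highest density 10 or more, 85.8% (83.3 to 88.0) of the 865 present in the full 8 h list and 70.6% (68.0 to 73.2) of the 1226 absent from it overlapped Ikaros at 8 h, and kept hotspots were higher in 5 of 5 quintiles, by between 2.81 and 30.5 percentage points. For Ikaros at 3 h they were higher in 2 of 5, with 74.1% (69.4 to 78.5) against 57.4% (42.2 to 71.7) in the strongest quintile. In wild-type cells, with the Ikaros 8 h list held to the length of the 3 h list by z score, 67.2% (64.8 to 69.5) of kept and 39.4% (37.8 to 41.1) of other RelA hotspots overlapped it, with kept hotspots higher in 5 of 5 quintiles. The Ikaros list is that of wild-type cells in both series.

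**Figure D4:**
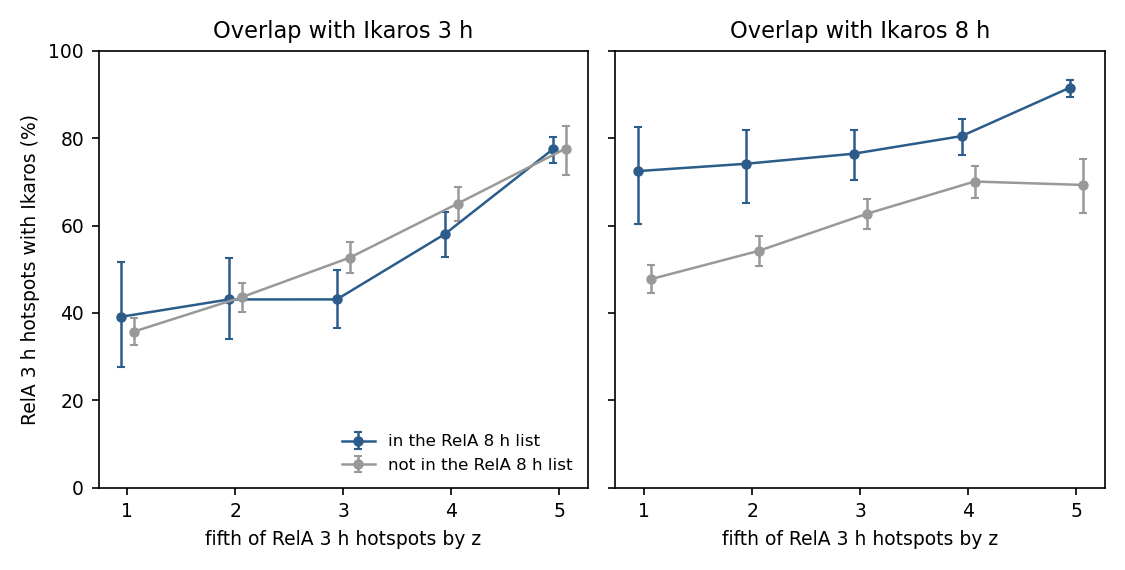
Share of wild-type RelA 3 h hotspots, in %, that overlap an Ikaros hotspot at 3 h (left) or 8 h (right), by quintile of RelA z score from 1 (weakest) to 5 (strongest), for hotspots present in the RelA 8 h list (blue) and absent from it (grey), with 95% exact intervals as bars. For Ikaros at 8 h the kept hotspots lie above the others in each quintile, at 72.5% against 47.7% in the weakest and 91.5% against 69.3% in the strongest.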

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

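The tests in this part were chosen after the results were seen, except the number of hotspots per library, which was fixed before. The number of RelA hotspots moved in opposite directions between 0 and 8 h in the series, by +1831 hotspots in wild-type cells (47 to 1878) and by -574 hotspots in littermate cells (5805 to 5231). The difference was not tested, since each series has 1 library per time. With hotspots of highest density 10 or more alone, both series rose, from 37 to 1863 in wild type and from 265 to 1026 in the littermate series.

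The opposite direction comes from littermate hotspots below a highest density of 10, of which there were 5540 at 0 h and 4205 at 8 h. Of the 7939 such hotspots deposited at 3 h, 0.390% overlapped a wild-type input hotspot. The input list held only 765 hotspots, too few to be the source of most of them. The share therefore does not bear on input background below its threshold, and the input of the littermate animals was not used here. Random placement of every such call is argued against, since 7.78% (7.20 to 8.39) of those at 3 h recurred at 0 h and at most 0.278% did after random shifts. The X chromosome held 9.46% (8.82 to 10.1) of them, against 2.53% (1.90 to 3.30) of denser 3 h hotspots and 6.31% of chromosome length, and the cause of that was not tested. Random placement of the calls that did not recur stays open, as do RelA sites particular to the littermate animals, on which the 1.10% (0.882 to 1.36) found in the wild-type 3 h list does not bear because such sites would be missing there.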

How the results depend on the processing

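No test is attached to these values, and a share counts as moved when it leaves the main 95% interval and a number of hotspots when it changes by over 1.5 times. Over 36 results, 97 of 189 alternatives left the value within these bounds and 92 moved it. Of 136 differences between times, a comparison added after the data were seen, 15 turned direction. The littermate list rose from 0 to 8 h with the density floor (265 to 1026). RelA with Ikaros fell from 3 to 8 h in both series with equal lists by z score or density, which the setting favours, since it holds the Ikaros list to a far smaller part at 8 h (in wild type 1878 of 13796 hotspots) than at 3 h (4972 of 7109). With Ikaros held to 7109 at both times by z score, the share rose from 54.0% to 61.8% in wild type and was 12.6% and 12.8% in the littermate series. Ikaros 0 h hotspots were present less often at 8 h than at 3 h under reciprocal overlap. The other 9 concern shares between series: wild-type hotspots found in the littermate list rose from 0 to 3 h with equal lists by z score, and from 0 to 8 h with equal lists by z score or density and with the upper 50% (54.2% to 57.0%), and littermate hotspots found in wild type fell from 0 to 3 h with equal lists by density and rose from 3 to 8 h with the floor, both equal lists and the upper 50% (17.0% to 20.5%). No paired analysis was possible because the labels give no shared replicate numbers and these values come from no test. A model of time across the 2 RelA series, whose genotype labels differ, was not run. Each group has 1 library, so none could be left out. The planned gene list and promoter counts and their distance alternatives were not run. Depth is unknown, so the least enrichment each library could show is too. The floor at a highest density of 10, equal lists by density, removal of broad hotspots, the wild-type series alone, the upper 50% for shares between series and with Ikaros, and all alternatives for the kept sites, for 8 h RelA at 3 h and for regions in both series were added after the data were seen. The cause was not tested except where the construction shows it, as in lists shortened by definition.

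As deposited, the wild-type RelA 0 h list held 83 hotspots, 1.06% of wild-type RelA 3 h hotspots were present at 0 h, and 45.8% of wild-type RelA 0 h hotspots were in the littermate list.

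With the upper 50% of each list by z score, RelA lists held 24, 2486 and 939 hotspots in wild type and 2904, 5000 and 2616 in the littermate series at 0, 3 and 8 h, and Ikaros lists 427, 3555 and 6898. RelA 3 h hotspots present at 8 h were 32.7% in wild type and 16.1% in the littermate series, and 8 h hotspots present at 3 h were 87.1% and 30.9%. Between series at 8 h the shares were 57.0% of wild-type and 20.5% of littermate hotspots. Ikaros 0 h hotspots present at 8 h were 91.8%. RelA hotspots with Ikaros were 20.8%, 46.7% and 70.1% in wild type at 0, 3 and 8 h, and 10.4% and 19.1% in the littermate series at 3 and 8 h. The excess of Ikaros at 8 h in kept RelA hotspots, 26.3 percentage points in the main setting, was 22.4. Regions in both series at 3 h numbered 763 absent at 0 h and 190 absent at 8 h.

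With the density floor, littermate lists held 265, 2091 and 1026 hotspots, with 7.17% of 3 h hotspots present at 0 h, 40.8% at 8 h, and 83.1% of 8 h hotspots present at 3 h. Of littermate hotspots, 10.6%, 78.1% and 80.1% were in the wild-type lists at 0, 3 and 8 h, and 14.3%, 57.7% and 79.4% carried Ikaros. Of wild-type 0 h hotspots, 75.7% were in the littermate list.

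Under a reciprocal overlap of 50%, RelA 3 h hotspots present at 0 and 8 h were 0.382% and 27.8% in wild type and 5.50% and 11.8% in the littermate series, and 8 h hotspots present at 3 h were 73.7% and 22.5%. Between series, wild-type hotspots found were 29.9% at 3 h and 40.6% at 8 h, and littermate hotspots found were 14.9% and 14.6%. Ikaros 0 h hotspots present at 3 and 8 h were 68.3% and 62.7%, those of 3 h present at 0 and 8 h were 8.20% and 69.9%, and those of 8 h present at 0 and 3 h were 3.88% and 36.0%. RelA hotspots with Ikaros at 3 and 8 h were 42.1% and 61.4% in wild type and 10.1% and 11.7% in the littermate series, and the excess in kept hotspots was 32.1 points.

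Within 500 bp, littermate RelA 3 h hotspots present at 0 and 8 h were 10.6% and 16.8%, and those of 8 h present at 3 h were 31.5%. Ikaros 3 h hotspots present at 8 h were 83.7%, those of 8 h present at 3 h were 44.2%, and wild-type RelA 3 h hotspots with Ikaros were 56.1%.

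With lists of equal length by z score, the shares between series were 19.1%, 19.2% and 29.7% in either direction at 0, 3 and 8 h. RelA hotspots with Ikaros were 4.26%, 44.5% and 27.8% in wild type and 2.11%, 13.7% and 11.1% in the littermate series. By highest density, 38.3% of wild-type 0 h hotspots were in the littermate list, littermate hotspots found in wild type were 38.3%, 34.8% and 44.0%, and those with Ikaros were 6.38%, 43.1% and 27.3% in wild type and 4.57%, 17.8% and 11.4% in the littermate series. Without broad hotspots, 52.2% of wild-type RelA 3 h hotspots carried Ikaros. In the wild-type series alone, 4935 RelA 3 h hotspots were absent at 0 h and 3416 at 8 h.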

Other observations

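The tests in this part were chosen after the results were seen, except the number of hotspots per library and the shares of RelA 0 h hotspots with Ikaros in full lists and in lists of equal length by z score, which were fixed before. The Ikaros lists after LPS held a small set of very wide hotspots. Hotspots of 2000 bp or more numbered 1 at 0 h, 47 at 3 h and 40 at 8 h in the Ikaros lists, 22 in the wild-type RelA list at 3 h and 1 at 8 h. Input DNA had 24 among its 765 hotspots, and hotspots that overlapped input were removed from the other lists. The widest Ikaros hotspot at 3 h spanned 10296 bp on chromosome 12 at 27125445 to 27135741, followed in width by chromosome 14 at 103450319 to 103459810, chromosome 11 at 83336475 to 83344401 and chromosome 16 at 97666525 to 97673256. At 8 h the widest was that on chromosome 14, at 103450329 to 103459869. Of the 47 at 3 h, 45 overlapped a RelA 3 h hotspot, 95.7% (85.5 to 99.5), against 36.7% (35.5 to 37.8) of narrower Ikaros hotspots, a comparison in which width itself raises the chance of overlap. Conversely, each of the 22 broad RelA hotspots at 3 h overlapped Ikaros at 3 h.

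RelA hotspots that appeared at 8 h without one at 3 h numbered 302 in wild-type cells. Of these, 60.3% (54.5 to 65.8) overlapped Ikaros at 8 h and 14.2% (10.5 to 18.7) Ikaros at 3 h, against 84.3% (82.4 to 86.1) and 63.4% (61.0 to 65.8) of the 1576 RelA 8 h hotspots already present at 3 h. The 302 were weaker, with a median z of 13.1 against 17.4. Within quintiles of z score the hotspots already present had the higher share with Ikaros at 3 h in 5 of 5, by at least 35.8 percentage points, and with Ikaros at 8 h in 4 of 5. The exception was the strongest quintile, which held only 5 of the 302, and the next held 18. The littermate 3 h list held 28.5% (23.5 to 33.9) of the 302 and 74.8% (72.6 to 76.9) of the 1576. The littermate 8 h list held 15.2% (11.4 to 19.8) and 49.5% (47.0 to 52.0) of them. Of the RelA hotspots of resting wild-type cells, 17 of 47 overlapped Ikaros at 0 h, 36.2% (22.7 to 51.5), and 4.26% did when the Ikaros list was held to its 47 strongest hotspots by z score. In the littermate list at 0 h the share was 0.689%, and 14.3% with the density floor. Of the input hotspots, 30.7% lay on the X chromosome and 10.3% on the Y chromosome, against 2.51% and 0.0399% of the deposited wild-type RelA 3 h hotspots. The deposited wild-type RelA 0 h list lay between, at 13.3% on X and 3.61% on Y, and the littermate lists had 9.22%, 8.23% and 8.07% on X at 0, 3 and 8 h.

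The growth of the Ikaros list after LPS, to 16.2 times its 0 h length at 8 h, may reflect recruitment or a less sensitive library at 0 h. If the 0 h library only missed the weaker sites of a fixed order, its list would hold the strongest 3 h sites. It held 71.0% (64.2 to 77.2) of the 200 strongest narrow 3 h hotspots, and the 853 strongest 8 h hotspots held 80.5% (74.3 to 85.8) of the same 200. These shares were not compared in a paired test. With 1 library per time, lower sensitivity and recruitment cannot be told apart for narrow sites. Of the broad hotspots, 10 of 47 were in the 0 h list, 21.3% (10.7 to 35.7), against 53.7% (46.0 to 61.2) of 177 narrow hotspots of like z score. This argues against a fixed order by z score alone. It does not bear on a 0 h library that misses wide regions more readily than narrow ones, since width was not matched.

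The overlap of RelA with Ikaros at 3 h may reflect both factors at the same sites or open chromatin that any antibody recovers. Width of the stronger RelA hotspots as the cause of the rise with strength is argued against, since hotspots narrowed to their central 250 bp still overlapped Ikaros in 77.1% (74.3 to 79.6) of the strongest quintile and 36.0% (33.0 to 39.1) of the weakest. Overlapping centres lay a median of 66.5 bp apart, against 283 bp for overlaps after random shifts, as both factors at the same sites would give and as shared open chromatin would give too. Centres of overlapping wild-type and littermate RelA 3 h hotspots lay closer, a median of 43.0 bp apart. The quartiles were 18.0 and 81.5 bp there, and 30.5 and 129 bp for RelA with Ikaros. Stronger Ikaros hotspots carried RelA more often, at 22.0% (19.9 to 24.3) in the weakest quintile and 55.7% (53.0 to 58.3) in the strongest. Open chromatin would give this rise, and both factors at the same sites could give it too, so it does not part them. The narrow Ikaros regions without RelA named on chromosomes 8, 10, 3 and 13 belong to the strongest Ikaros quintile, and no profile of a control antibody or of accessibility was used here.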
